A study of Mus musculus with 48 samples.

How the data were processed

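The deposited files hold 48 libraries of bone marrow-derived macrophages from 16 mice, 4 mice per genotype (2 male and 2 female), each treated 3 ways. Per the labels' protocols, marrow was cultured with M-CSF, the cells were rested overnight without M-CSF, and they were left without ligand (NT) or treated with LPS or R848 for 2 h. RNA was selected by polyA and sequenced as pairs of reads. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and DESeq2 were used with build GRCm38. The role of each tool is inferred from its name. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping, antisense and paralogous genes are uncertain.

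The authors deposited a table of raw counts (unit: counts, whole numbers per Ensembl gene, not normalized), which was used for all tests. A second deposited table holds variance-stabilised values on a log2 scale made by the authors with DESeq2, of 13617 genes between 6.18 and 19.29. It was not used for tests. Its Spearman correlation with the counts was at least 0.99989 in each library, across genes, which are not independent replicates. The count table has 49315 genes, of which 49056 matched the GENCODE M21 annotation by identifier and 17515 had no count in any library. Total counts per library were 14974764 to 23321447. Floors and counting intervals cover counting error only.

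Comparisons, tests, gene lists and most alternatives were fixed before the data were examined. Genes were kept by filterByExpr over the 12 groups (minimum count 10, minimum total 15), which left 13986 genes. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, and p was adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. There were 32 comparisons. The 8 ligand comparisons used the 12 libraries of a genotype. The 18 genotype comparisons used the 16 libraries of a treatment, each from a different mouse by the labels. The 6 differences of a ligand response from WT used all 48 libraries in 12 groups. A ± after a log2 fold change is its SE from edgeR, and a ± after CPM the SD of 4 libraries. CPM are scaled by TMM, except those of Ifnb1, Xist and the Y-linked genes, which use the total counts of a library.

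Of 38 gene lists with 817 genes written in advance, 33 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. The lists of type I interferons, T and NK cells, eosinophils and erythroid cells had fewer than 3 tested members and were not tested, and the sex check genes were used only to check sex. The words NF-kB feedback regulators name a list here, which also holds NF-kB target genes that are not feedback regulators, such as Sod2 and Icam1. Count statements for a list give members past the threshold over all genes and members adjusted over the list alone. The score of a list in a library is the mean log2 CPM of its members with a prior count of 2, compared by an exact two-sided permutation test of 4 against 4 libraries, whose smallest p is 0.0286, in a family of 72 tests. Calls that share control libraries were set against 10 simulations of unchanged groups with the same controls, and against controls split between the comparisons.

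Genes were named by a rule: Lyn, a fixed set of cytokine, interferon and cell cycle genes, up to 3 members each way of each list described, and up to 5 genes each way with the largest change among genes past the threshold with non-overlapping groups and a mean of at least 5 CPM, at most 30 per comparison. Where 10 or fewer genes passed, all were named, and where none passed, the 3 with the smallest p. Where the rule allowed more genes than were named, those named were chosen after their values were seen, as were the genes of the further observations, which go past the limit of 30. Some genes that the rule gives are not reported here.

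The model was tested on simulated data with 200 changed genes added to each of 3 designs. Of genes changed 2-fold, edgeR recovered 77.6% for LPS against NT in WT, 76.1% for LynKO against WT and 71.6% for the LPS response of LynKO, with 10, 11 and 9 false calls. The moved list was called in each, with 0, 0 and 1 of the other lists called.

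The alternatives were DESeq2 1.42.0 with its own size factors, RLE size factors, no filter on low counts, sex as a covariate, the replicate number as a block, all 48 libraries in 1 model, only the 4 groups of a contrast, and each mouse left out in turn. The setting with no filter on low counts was not tested on simulated data. In it many named genes had a far smaller p at nearly the same log2 fold change, so a pass there alone is weak. The replicate number stands for the mouse in ligand comparisons and responses, by the labels. In LynBKO the sex labels of NT 2 and NT 3 are exchanged against those of the LPS and R848 libraries, so the block was also fitted with these numbers exchanged. Within WT, LynAKO and LynKO the libraries with the same number correlated above 0.1 in 11, 12 and 11 of 12 pairs after removal of group means, and in 5 of 12 in LynBKO, across genes. Between genotypes the numbers stand for different mice, but libraries with the same number correlated above 0.1 in 8 of 24 pairs without ligand, 14 with LPS and 17 with R848. The third principal component placed number 3 at 6.5 to 11.6 and number 4 at 14.3 to 17.9 in all libraries except LynBKO NT and LynKO NT 4. The numbers share the sex label, 1 and 2 being male and 3 and 4 female in every group except LynBKO NT. On this component numbers 1 and 2 lay below 0 and numbers 3 and 4 above 0 outside LynBKO NT, where number 2, labelled female, lay at 10.7. What else the numbers share between genotypes, and what sets number 3 apart from number 4, is not given in the sources used here. Leaving out the LynBKO NT 4 and LynKO NT 4 libraries, which hold male and female transcripts together, was chosen after the data were seen. No library was left out of the values in the report. The first principal component of 2000 genes held 74.9% of the variance and the second 8.4%. No pair of libraries within a group was a duplicate, the lowest of 72 values of chi-square per degree of freedom being 5.32.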

Results

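Bone marrow-derived macrophages were profiled by polyA RNA sequencing in 4 genotypes of mouse: wild type (WT), a knockout of the LynA splice isoform (LynAKO), a knockout of the LynB isoform (LynBKO) and a total knockout (LynKO). Lyn is a Src-family tyrosine kinase that phosphorylates both activating and inhibitory receptors of myeloid cells. Cells of 4 mice per genotype (2 male, 2 female) were kept without ligand (NT) or treated for 2 h with 2 ng/mL lipopolysaccharide (LPS), a ligand of Toll-like receptor 4, or 20 ng/mL resiquimod (R848), a ligand of Toll-like receptor 7 in mouse cells. This gave 12 groups of 4 libraries and 48 libraries in all, with 14974764 to 23321447 counts per library. The title of the series names the questions: how Lyn bears on Toll-like receptor activation and on proliferation in macrophages, and whether the isoform matters.

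Lyn itself (ENSMUSG00000042228, GRCm38 chromosome 4, 3678115 to 3813122, plus strand) was lower in every knockout group than in WT. Without ligand it stood at 177 ± 10.4 CPM (counts scaled to library size, mean ± SD, n = 4) in WT, 118 ± 11.5 in LynAKO, 125 ± 6.38 in LynBKO and 67.6 ± 4.15 in LynKO. In LynKO against WT its log2 fold change was -1.38 ± 0.07 (SE) without ligand, -1.89 ± 0.09 with LPS and -1.84 ± 0.09 with R848 (edgeR adjusted p = 2.76e-10, 2.79e-11 and 2.39e-10). In LynAKO it was -0.58 ± 0.07, -0.64 ± 0.09 and -0.61 ± 0.09, and in LynBKO -0.50 ± 0.07, -0.65 ± 0.09 and -0.55 ± 0.09, in the same order of treatments. The LynBKO difference with R848 had an edgeR adjusted p of 0.0504. It passed by DESeq2 (8.67e-06), with sex as a covariate (0.0428), with the replicate number as a block (0.00976), with all 48 libraries in 1 model (0.000533) and with no filter on low counts (2.02e-05). It also passed without WT 2, LynAKO 4, LynKO 2 or LynKO 4 (0.0328, 0.0458, 0.0225 and 0.0431). The LynAKO difference with R848 (0.0133) lost its call without LynAKO mouse 1 (0.116) or LynAKO mouse 3 (0.0802). The counts are per gene, so the isoforms were not told apart, and LynKO cells kept reads at the locus.

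**Figure D1:**
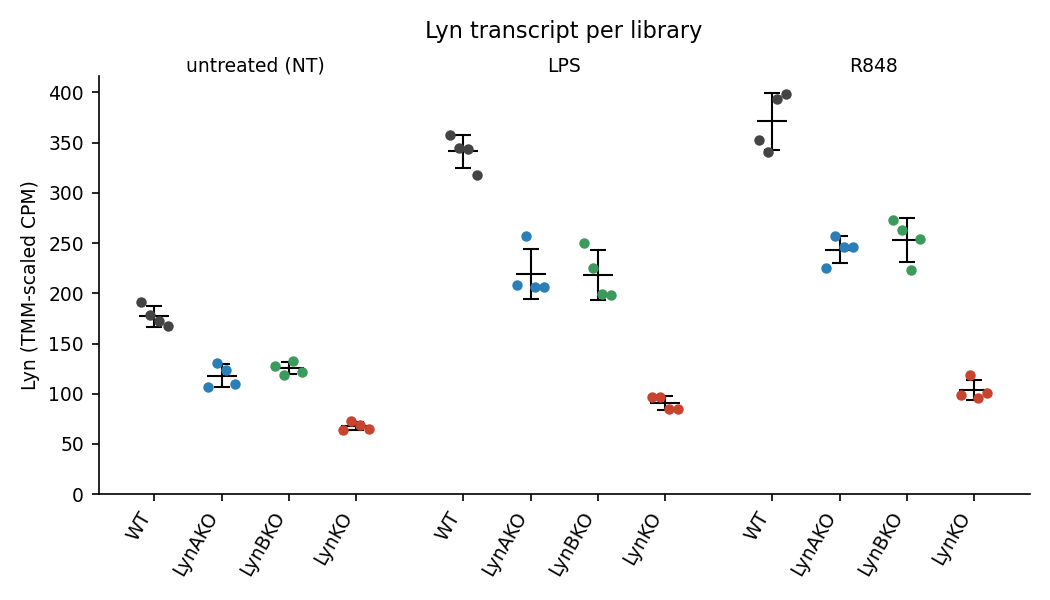
Lyn transcript in each of the 48 libraries, in TMM-scaled CPM on a linear axis that starts at 0; each point is 1 library, the bar is the group mean and the error bar the SD (n = 4). All 4 LynKO libraries lie below all libraries of the other genotypes within each treatment, at 67.6 CPM without ligand against 177 CPM in WT.

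LPS raised cytokine, chemokine and interferon-response genes in WT macrophages. Tnf, an early inflammatory cytokine, went from 17.3 ± 3.03 to 2750 ± 260 CPM (SD, n = 4 each), Il1b rose by 6.42 ± 0.21 on the log2 scale (SE) and Il1a by 9.49 ± 0.27 (edgeR adjusted p = 6.94e-15, 2.15e-14 and 3.65e-15). Il6 reached 72.5 ± 10.6 CPM and Il12b, which encodes the p40 subunit of interleukin-12, 60.5 ± 11.3 CPM, from 2 and 1 counts in all 4 untreated WT libraries together. The interferon gene Ifnb1 had no count in these 4 libraries. Its 0.664 CPM with LPS, not scaled by TMM, was at least 18.7-fold above the floor of 3 counts over the group (0.0356 CPM, counting error only). Lyn rose as well, by 0.96 ± 0.08 (adjusted p = 6.14e-09).

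In the inflammatory cytokine list 20 of 22 members rose and Osm fell by 1.19 ± 0.17 on the log2 scale, with the same numbers when adjusted over the list alone. Of the chemokines, 19 of 20 rose, among them Cxcl10 (8.51 ± 0.32), Cxcl2 (7.51 ± 0.20), Ccl5 (7.98 ± 0.34) and Ccl22 (7.22 ± 0.23). All 54 interferon-stimulated genes rose, with Ifit1 at 5.59 ± 0.31, Gbp5 at 8.73 ± 0.23 and the RNA sensor Ifih1 at 3.80 ± 0.09. All 28 members of the NF-kB feedback regulator list rose, with Nfkbia, the inhibitor of NF-kB, at 3.85 ± 0.10, Tnfaip3 at 6.38 ± 0.12 and Icam1 at 4.92 ± 0.09. The counts of these 3 lists were the same adjusted over the list alone. Of 46 G1/S and DNA replication genes, 30 fell and 1 rose (30 and 1 adjusted over the list alone), including the licensing factor Cdt1 (-2.86 ± 0.15) and E2f2 (-3.79 ± 0.24). The G2/M list was divided, with 8 of 53 members up and 13 down (7 and 13 adjusted over the list alone). Mki67, which encodes the Ki-67 proliferation antigen, rose by 3.53 ± 0.18, and the centromere histone gene Cenpa had a log2 fold change of -1.98 ± 0.13. Hypoxia and glycolysis genes rose in 21 of 29 cases (22 adjusted over the list alone), led by Pfkfb3 (4.94 ± 0.18). The receptor genes Cnr2 (-7.90 ± 0.34), Lpar6 (-7.15 ± 0.21) and Cxcr4 (-6.49 ± 0.15) were among those that fell. In total edgeR called 8609 of 13986 genes, 4407 higher and 4202 lower. The camera calls of the cytokine, chemokine, interferon, NF-kB, G1/S and glycolysis lists, made with a preset correlation, gave adjusted p = 0.142, 0.142, 0.189, 0.0763, 0.410 and 0.434 with an estimated correlation.

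R848 raised much of the same set in WT cells but not the interferon-stimulated genes as a group. Tnf reached 2690 ± 809 CPM and Il12b 124 ± 42 CPM (SD, n = 4), Il1b rose by 6.41 ± 0.21 and Cxcl2 by 8.13 ± 0.20 (log2, SE; edgeR adjusted p = 3.87e-14 and 1.11e-15). Cxcl10 rose by 2.71 ± 0.26, to 49.5 ± 17.9 CPM against 2770 ± 285 CPM with LPS. Of 54 interferon-stimulated genes, 16 rose and 10 fell (16 and 10 adjusted over the list alone; camera adjusted p = 0.476). Gbp5 rose by 6.07 ± 0.21, Ifit3 fell by 1.08 ± 0.21, and Ifit1 was at 0.03 ± 0.28 (adjusted p = 0.934). R848 and LPS were not tested against each other.

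All 28 NF-kB feedback regulators rose with R848, as did 18 of 22 cytokines and 17 of 20 chemokines, while Osm fell by 1.35 ± 0.17. The numbers were the same adjusted over the list alone, and the calls had adjusted p = 0.0692, 0.151 and 0.229 with an estimated correlation. Socs3, a feedback inhibitor of cytokine signalling, rose by 7.38 ± 0.17, Tnfaip3 by 5.49 ± 0.11 and Cxcl1 by 9.01 ± 0.31. Of the G1/S list 23 of 46 fell and 1 rose (23 and 1 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation), and Mki67 rose by 3.24 ± 0.18. Cholesterol synthesis genes rose in 15 of 22 cases and fell in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.564 with an estimated correlation), among them the sterol pathway enzyme gene Hmgcs1 (1.81 ± 0.15). NRF2 targets rose in 12 of 20 and fell in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.506 with an estimated correlation), with Txnrd1 at 2.31 ± 0.10 and Sqstm1 at 2.14 ± 0.10. Lyn rose by 1.10 ± 0.08. edgeR called 7935 genes, 4199 higher and 3736 lower. Ifnb1 passed with R848 at an adjusted p of 0.0468 and lost that call without WT 1, 2, 3 or 4 (0.107, 0.109, 0.0639 and 0.135). It also lost the call with no filter on low counts (0.0659).

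Both ligands were compared with the same untreated libraries. They shared 6646 genes called with the same sign (3546 higher, 3100 lower) and 103 with opposite signs. Independent lists would share 2450 with the same sign. Of the genes called with R848, 96.2% had the same sign with LPS. For unchanged groups simulated against these controls it was 72.8%, over as many genes with the smallest p. The covariance of the log2 fold changes was 1.34 against 0.0309 in the simulation. With the untreated libraries split between the comparisons, 5455 and 5484 genes were shared.

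Tnf, Cxcl10 and Nfkbia also rose in the knockout macrophages. With LPS, Tnf rose by 7.72 ± 0.19 in LynAKO, 7.56 ± 0.15 in LynBKO and 7.65 ± 0.23 in LynKO (log2, SE, n = 4 against 4; edgeR adjusted p = 1.5e-15, 6.82e-17 and 1.04e-13), and Cxcl10 by 9.19 ± 0.29, 8.55 ± 0.17 and 9.96 ± 0.21. With R848, Nfkbia rose by 3.58 ± 0.09, 3.56 ± 0.08 and 3.79 ± 0.11, while Ifit1 was at 0.13 ± 0.25, -0.08 ± 0.18 and 0.03 ± 0.20, past the test in none. All 54 interferon-stimulated genes rose with LPS in each knockout (54 adjusted over the list alone; adjusted p = 0.287, 0.404 and 0.278 with an estimated correlation in LynAKO, LynBKO and LynKO). All 28 NF-kB feedback regulators rose with LPS in each (28 adjusted over the list alone; adjusted p = 0.00928, 0.105 and 0.0519 with an estimated correlation), as did 20 of 22 cytokines, while 1 fell (20 and 1; adjusted p = 0.142, 0.165 and 0.0825 with an estimated correlation). edgeR called 8484, 9412 and 8629 genes with LPS and 7828, 8878 and 7738 with R848 in LynAKO, LynBKO and LynKO.

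Without ligand, LynKO macrophages carried more transcripts of the cell cycle than WT. Top2a, a topoisomerase of dividing cells, stood at 45.9 ± 3.94 CPM in LynKO and 16.6 ± 5.64 in WT (SD, n = 4), and Mki67 at 56.1 ± 7.53 and 27.9 ± 7.44 (log2 fold changes 1.48 ± 0.17 and 1.02 ± 0.15, SE; edgeR adjusted p = 1.13e-05 and 0.000194). The mitotic cyclin gene Ccnb1 rose by 1.08 ± 0.15, the replication helicase gene Mcm5 by 1.23 ± 0.18, the G1 cyclin gene Ccnd1 by 1.35 ± 0.31, Anln by 1.43 ± 0.17 and the ribonucleotide reductase gene Rrm2 by 1.81 ± 0.25. Of the G2/M list 49 of 53 members rose and none fell (50 adjusted over the list alone), and of the G1/S list 31 of 46 rose (35 adjusted over the list alone). Camera called both upward (adjusted p = 6.52e-41 and 4.69e-21), and both calls held with an estimated correlation (adjusted p = 0.041 each).

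Il1b, Tnf and several members of the NF-kB feedback regulator list were lower in these untreated LynKO cells. Il1b fell by 1.77 ± 0.28 and Tnf by 0.92 ± 0.16, to 9.07 ± 2.47 CPM (SD, n = 4). Il6 and Il12b were near 0 in both groups, with 1 and 0 counts in all 4 LynKO libraries. Of the NF-kB feedback regulators 13 of 28 fell and 1 rose (16 and 2 adjusted over the list alone; adjusted p = 0.041 with an estimated correlation), with Sod2 at -0.86 ± 0.08 and Tnfaip2 at -0.86 ± 0.09 (edgeR adjusted p = 3.44e-06 and 8.68e-06). The member that rose was Zfp36 (0.34 ± 0.08), a factor that destabilizes cytokine mRNA. Its call was lost without the LynBKO NT 4 and LynKO NT 4 libraries and with all 48 libraries in 1 model (adjusted p = 0.0569 and 0.066). Cytokines fell in 5 of 22 cases (6 adjusted over the list alone; adjusted p = 0.163 with an estimated correlation). Chemokines fell in 5 of 20 (6; adjusted p = 0.279 with an estimated correlation), including Cxcl10 (-1.65 ± 0.30). Activating receptors and their adaptors fell in 8 of 23 (12 fell and 1 rose adjusted over the list alone; adjusted p = 0.243 with an estimated correlation), led by the C-type lectin genes Clec4n (-1.93 ± 0.19) and Clec4e (-0.72 ± 0.10). Inhibitory receptors fell in 11 of 22 and rose in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.297 with an estimated correlation), with the Fc receptor gene Fcgr2b at -0.79 ± 0.08 and Cd72 at 0.72 ± 0.10. The Src-family relative Fgr (-0.37 ± 0.11, adjusted p = 0.0333) and the M-CSF receptor gene Csf1r (-0.21 ± 0.07, 0.0493) passed narrowly. Without WT 3, WT 4, LynKO 1, 2, 3 or 4 the call of Fgr was lost (adjusted p = 0.094, 0.125, 0.0804, 0.0564, 0.0598 and 0.0826). Without WT 1, 2, 3 or 4, LynBKO 2, 3 or 4 or LynKO 1, 2 or 4 the call of Csf1r was lost (0.12, 0.0585, 0.0944, 0.0696, 0.053, 0.0626, 0.0635, 0.112, 0.071 and 0.151), as it was with sex as a covariate (0.0538). Without the LynBKO NT 4 and LynKO NT 4 libraries neither Fgr nor Csf1r passed (0.0995 and 0.179).

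Single macrophage and metabolic genes also changed without ligand, and none of their lists passed with an estimated correlation. Lyz2, which encodes lysozyme, fell by 0.78 ± 0.08, the TAM receptor ligand gene Gas6 fell by 0.74 ± 0.07, and the folate receptor gene Folr2 rose by 2.19 ± 0.30. Of 25 mature macrophage markers 7 fell and 2 rose (12 and 6 adjusted over the list alone; adjusted p = 0.279 with an estimated correlation). Lysosome genes fell in 12 of 35 and rose in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation), with Psap at -0.54 ± 0.06. Members of the unfolded protein and integrated stress response list fell in 10 of 24 (15 fell and 2 rose adjusted over the list alone; adjusted p = 0.0725 with an estimated correlation). NRF2 targets fell in 7 of 20 (7 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), with the cystine transporter gene Slc7a11 at -1.49 ± 0.18. In LXR targets and lipid handling 6 of 19 rose and 3 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.516), with the lipase gene Lpl at 1.32 ± 0.20. edgeR called 1385 genes in all, 760 higher and 625 lower in LynKO, and 962 without WT mouse 1. LynKO NT 4 held male as well as female transcripts (Y-linked genes at 89.6 CPM in cells labelled female), and so did LynBKO NT 4; without these libraries edgeR called 967 genes.

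**Figure D2:**
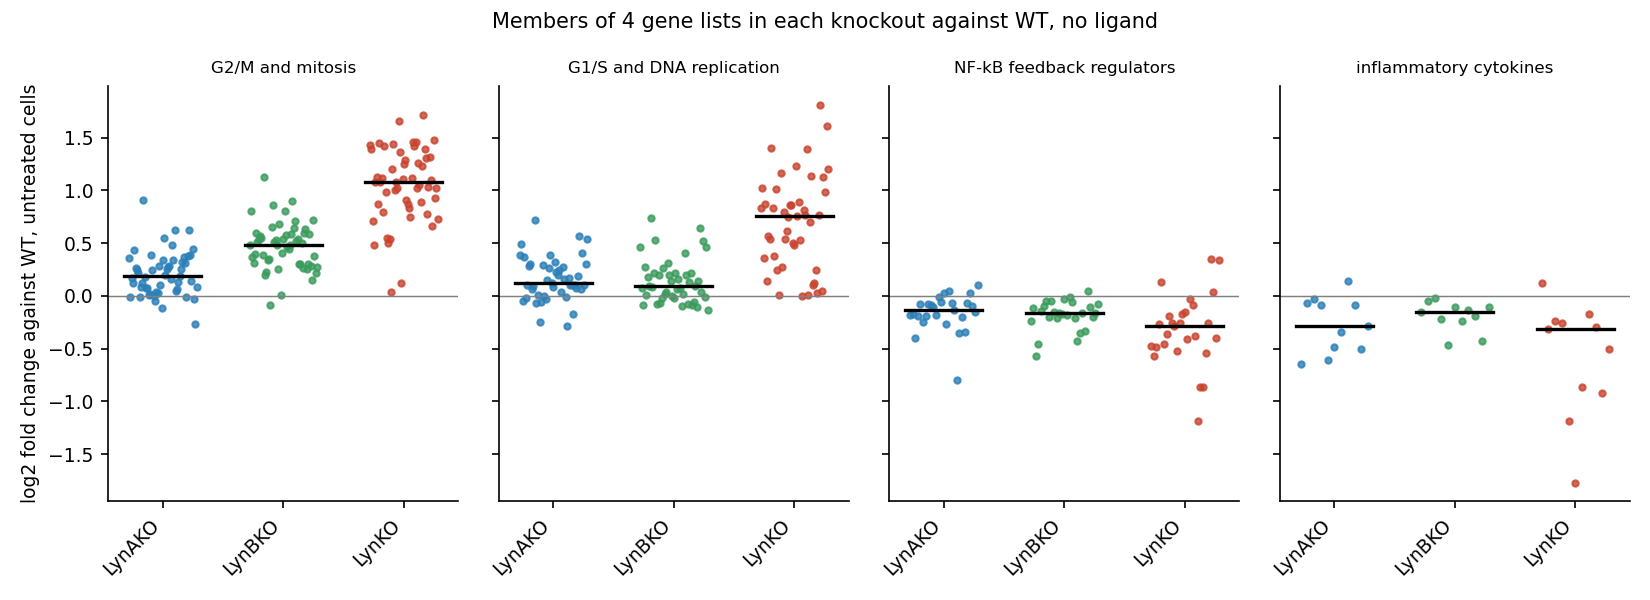
Log2 fold change against WT, in untreated cells, of the members of 4 gene lists in LynAKO, LynBKO and LynKO; each point is a gene and each black line the median of the points. Members whose highest untreated group mean was under 1 CPM are not drawn, a limit set after the plot was first seen (0 of 53 G2/M, 1 of 46 G1/S, 1 of 28 NF-kB and 11 of 22 cytokine members left out); the G2/M members of LynKO lie highest, and 49 of 53 passed the test.

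With LPS, LynKO cells again carried more cell cycle transcripts and less of several cytokines than WT. Top2a was higher by 1.16 ± 0.19 (log2, SE, n = 4 against 4), Mcm5 by 1.39 ± 0.22, Ccnd1 by 1.78 ± 0.32 and the mitotic kinase gene Pbk by 2.18 ± 0.35 (edgeR adjusted p = 0.000616, 0.000494, 0.00171 and 0.000652). Mki67 was at -0.20 ± 0.10 (adjusted p = 0.241). Of the G2/M list 35 of 53 were higher and 1, Hmgb2 (-0.42 ± 0.10), lower (46 and 1 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation). Of the G1/S list 26 of 46 were higher (32 adjusted over the list alone; adjusted p = 0.0573 with an estimated correlation). Il12b stood at 20.1 ± 5.14 CPM in LynKO against 60.5 ± 11.3 in WT (log2 fold change -1.57 ± 0.28, adjusted p = 0.00158), Tnf at -0.57 ± 0.12 (0.00453), Il1a at -0.69 ± 0.14 and Tnfsf15 at -1.35 ± 0.24. Il6 was at -0.72 ± 0.24 with an adjusted p of 0.062. It passed with the replicate number as a block (-0.76, 0.0336), with sex as a covariate (-0.74, 0.0392) and with no filter on low counts (9.27e-11). It also passed without LynAKO 2, LynAKO 4, LynBKO 1 or LynKO 1 (0.0429, 0.0464, 0.0439 and 0.0236). Cytokines were lower in 7 of 22 (12 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation) and NF-kB feedback regulators in 8 of 28 (19; adjusted p = 0.144 with an estimated correlation). Interferon-stimulated genes were higher in 2 of 54 (2 adjusted over the list alone; camera adjusted p = 0.605). Neutrophil and granulocyte progenitor markers were lower in 3 of 10 (7; adjusted p = 0.0573 with an estimated correlation), with Mmp8 at -1.52 ± 0.24. The collagen gene Col4a6 was higher by 3.03 ± 0.41. edgeR called 1187 genes (619 higher, 568 lower), 663 without WT mouse 1 and 747 without LynKO mouse 4.

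With R848 too, cell cycle transcripts were higher and Il12b was lower in LynKO than in WT. Top2a was higher by 1.11 ± 0.16 (log2, SE, n = 4 against 4), the cyclin gene Ccna2 by 1.04 ± 0.16, Tk1 by 0.91 ± 0.11 and Mcm5 by 1.09 ± 0.19 (edgeR adjusted p = 0.000556, 0.0014, 0.000158 and 0.00283), and Mki67 was at -0.27 ± 0.24 (adjusted p = 0.576, but 0.029 with the replicate number as a block, at -0.31). Il12b stood at 53.4 ± 17.7 CPM against 124 ± 42 in WT (-1.22 ± 0.22, adjusted p = 0.00359) and Il1b at -0.71 ± 0.16 (0.0141, but 0.0543 without WT 4 and 0.0514 without LynKO 1). Tnf was at -0.58 ± 0.20 (adjusted p = 0.0929) and Il6 at -0.94 ± 0.34 (0.107). Both passed with the replicate number as a block (0.00504 and 0.0333), with all 48 libraries in 1 model (0.0222 and 0.0295) and with no filter on low counts (8.12e-09 and 1.09e-10). Tnf also passed by DESeq2 (0.0384), with sex as a covariate (0.0221) and without WT 2 (0.0338). G2/M genes were higher in 39 of 53 and lower in 1 (46 and 1 adjusted over the list alone; adjusted p = 0.145 with an estimated correlation) and G1/S genes in 21 of 46 (31; adjusted p = 0.180 with an estimated correlation). Cytokines were lower in 5 of 22 (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.272 with an estimated correlation) and lysosome genes lower in 6 of 35 and higher in 1 (11 and 2; adjusted p = 0.264 with an estimated correlation). NF-kB feedback regulators were lower in 3 of 28 (6 adjusted over the list alone; adjusted p = 0.272 with an estimated correlation) and neutrophil markers in 2 of 10 (4; adjusted p = 0.194 with an estimated correlation). Col4a6 was higher by 3.14 ± 0.36 and the carboxypeptidase gene Cpe by 2.77 ± 0.24, while Clec4n was at -1.68 ± 0.18 and Mmp8 at -1.63 ± 0.20. edgeR called 829 genes (446 higher, 383 lower), 1753 with the replicate number as a block, and DESeq2 1250. Without WT 3, WT 4, LynKO 1 or LynKO 4 edgeR called 483, 464, 523 and 542.

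The mean log2 CPM of a list per library gave the same directions mouse by mouse. The G2/M score of LynKO exceeded that of WT by 1.07 without ligand, 0.93 with LPS and 0.86 with R848, with all 4 LynKO libraries above all 4 WT libraries each time. The G1/S score did so by 0.70, 0.83 and 0.76. Each had the smallest p that an exact two-sided permutation test of 4 against 4 allows, 0.0286, which became 0.229 after adjustment over 72 tests. An adjusted p under 0.05 would need most of the 72 tests at this smallest p. The adjusted value therefore says little for or against a difference. The cytokine score of LynKO was lower by a difference of -0.41 without ligand and -0.55 with LPS (all 4 below all WT libraries, exact p = 0.0286 each) and -0.43 with R848 (3 of 4 below all WT, exact p = 0.114). The permutation test makes no use of the replicate numbers. Part of the G2/M difference of LynKO from WT without ligand and with LPS came from WT 1. Its G2/M score was the lowest of WT in both, at 1.89 and 1.78, with the other WT libraries at 2.52 to 2.61 without ligand. The interferon score differed by -0.08, -0.02 and 0.12 (exact p = 0.714, 0.914 and 0.514).

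**Figure D3:**
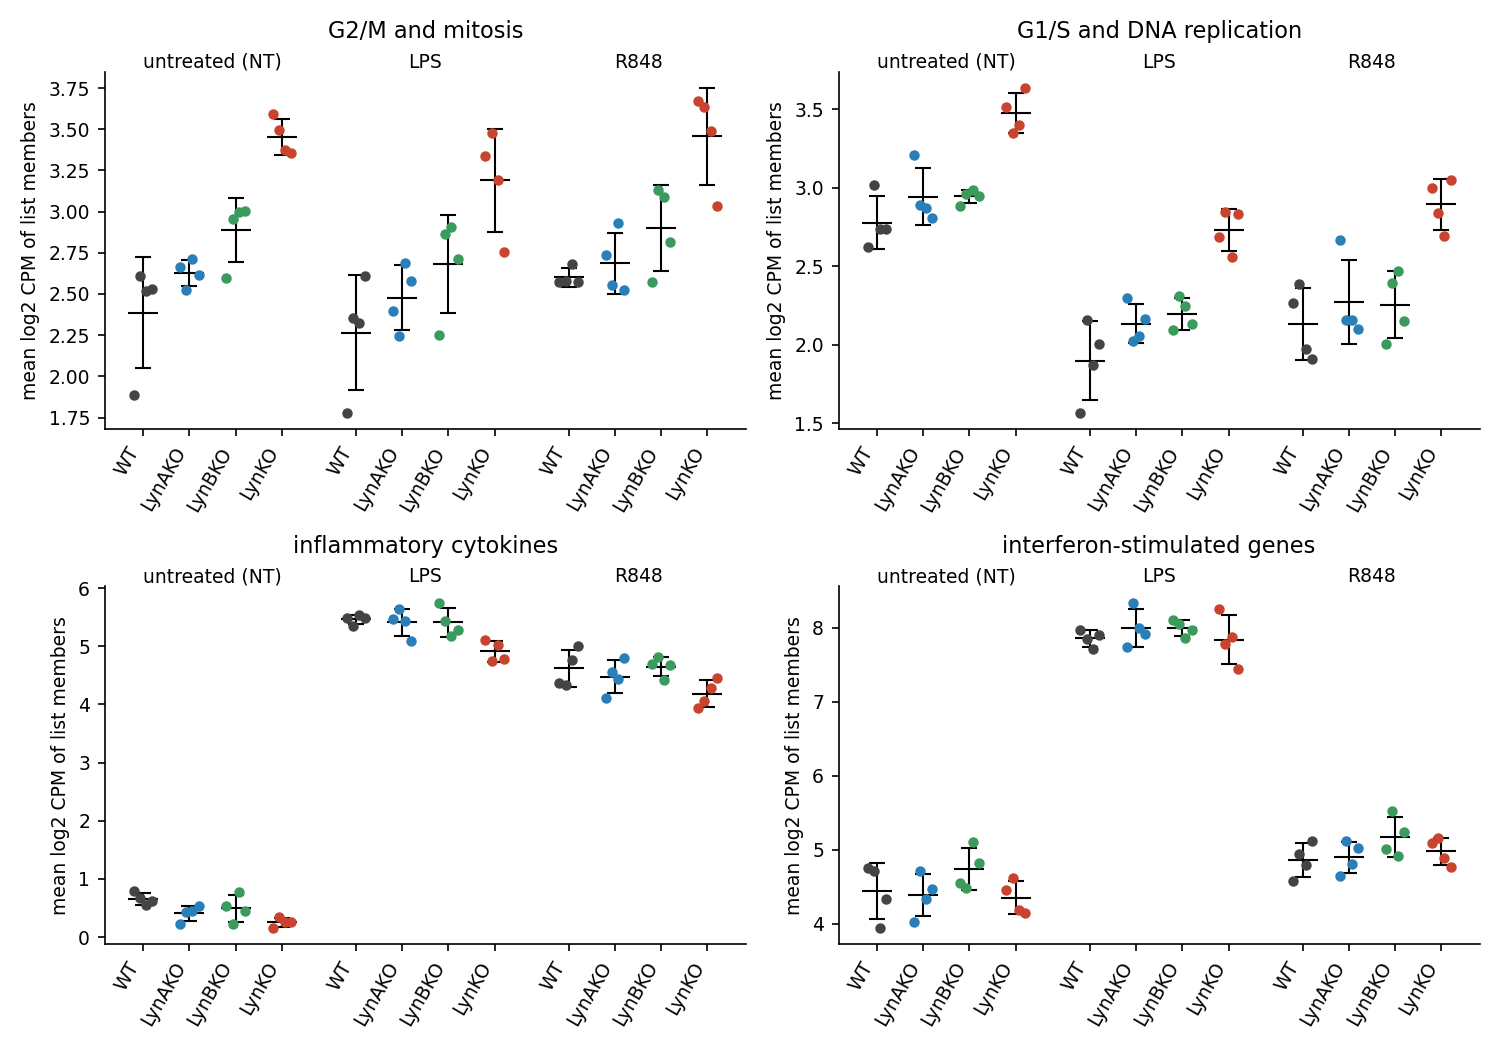
Mean log2 CPM (prior count 2) of the members of 4 gene lists in each of the 48 libraries; points are libraries, bars group means and error bars SD (n = 4), and the axes do not start at 0. The 4 LynKO libraries lie above the 4 WT libraries in the G2/M and G1/S panels in every treatment.

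With the filter on low counts, edgeR called few genes for the loss of a single isoform. In untreated LynAKO cells edgeR called 4 genes against WT: Lyn, Ide, which encodes insulin-degrading enzyme (-0.84 ± 0.12, SE, n = 4 against 4, adjusted p = 0.00704), Ap4s1 (0.77 ± 0.13, 0.0347) and Gm13835 (-1.62 ± 0.28, 0.0491). In untreated LynBKO cells it called 9: Lyn, the fatty acid binding protein genes Fabp4 (-0.97 ± 0.13, adjusted p = 0.00353) and Fabp5 (-0.50 ± 0.08, 0.0205), the integrin gene Itgb7 (0.82 ± 0.12, 0.00353), Gm13835 (-1.86 ± 0.29, 0.00915), Ide (-0.77 ± 0.12, 0.00915), Fam102a (0.45 ± 0.08), Havcr2 (0.51 ± 0.10) and Itpr3 (0.51 ± 0.09; the last 3 at 0.0454). Gm13835 is a predicted gene of low count, and whether counting used strand is not given in the sources used here, so its value is uncertain. Top2a stood at 0.44 ± 0.17 in LynAKO (adjusted p = 0.994) and 0.72 ± 0.17 in LynBKO (0.116), and Tnf at -0.50 ± 0.15 (0.704) and -0.43 ± 0.15 (0.269). In LynBKO Top2a passed by DESeq2 (0.00981) and without WT 2 (0.0231). With no filter on low counts Top2a passed in LynAKO and LynBKO (0.00369 and 2.27e-10) and so did Tnf (0.0136 and 0.0287). DESeq2 called 12 and 124 genes, and edgeR with no filter on low counts 124 and 445. At an unadjusted p under 0.05 there were 671 genes for LynAKO and 1849 for LynBKO. The LynAKO count was 7 without WT 3 and 2 without WT 1, WT 4, LynAKO 1, LynAKO 2, LynAKO 4, LynBKO 2, LynBKO 3 or LynKO 2. The LynBKO count was 14 without WT 2, 29 without WT 3, 4 without WT 4, 18 without LynAKO 4 and 3 without LynBKO 2, LynBKO 3 or LynBKO 4. Over up to 23 other settings, Lyn and Ide in LynAKO and Lyn, Fabp4 and Itgb7 in LynBKO passed each time. The other calls were lost in at least 1 of these settings (highest adjusted p = 0.204 for Ap4s1, 0.329 for Gm13835 in LynAKO and 0.0689 in LynBKO, 0.0689 for Ide in LynBKO, 0.114 for Fabp5, 0.188 for Fam102a, 0.2 for Havcr2 and 0.307 for Itpr3).

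In the edgeR fit with the filter on low counts and no library left out, no member of the G2/M list passed over all genes in either single knockout. Without ligand Top2a in LynBKO passed by DESeq2 (adjusted p = 0.00981) and without WT 2 (0.0231). Top2a (2.27e-10) and Mki67 (4.49e-06) in LynBKO and Top2a in LynAKO (0.00369) passed with no filter on low counts. In that setting Top2a in LynBKO passed with LPS and R848 too (0.000129 and 0.00647). Camera with a preset correlation placed the list higher in LynBKO without ligand (adjusted p = 1.77e-20, and 33 of 53 members rose adjusted over the list alone) and in LynAKO (6.94e-09, 0 members adjusted over the list alone by edgeR), but adjusted p = 0.242 and 0.456 with an estimated correlation. The G2/M score was higher by 0.50 in LynBKO and 0.24 in LynAKO, with 3 of 4 libraries above all WT libraries in each (exact permutation p = 0.0571 and 0.0857). Without WT 1 these differences were 0.33 and 0.08. With LPS and R848 the G2/M score was higher by 0.42 and 0.30 in LynBKO (exact permutation p = 0.114 and 0.0857). In LynAKO it was then higher by 0.21 and 0.09 (0.371 and 0.514). The cytokine score of untreated LynAKO differed from WT by -0.25, with all 4 libraries below all WT libraries (exact permutation p = 0.0286, 0.229 after adjustment), and that of LynBKO by -0.16 (exact p = 0.257), -0.07 without LynBKO 2 and -0.26 without LynBKO 3.

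With ligand, Lyn was again among the calls. In LynAKO with LPS edgeR called Lyn, the laminin gene Lama5 (1.53 ± 0.26, SE, n = 4 against 4, adjusted p = 0.0448) and Atad2b (-1.29 ± 0.17, 0.00234). In LynBKO with LPS it called Lyn, Lama5 (1.87 ± 0.26, 0.00254), Atad2b (-1.11 ± 0.16, 0.00587), Gm13835 (-1.55 ± 0.27, 0.0456) and Ide (-0.66 ± 0.12, 0.0498). With R848 it called only Lyn in LynAKO. In LynBKO with R848 edgeR called 0 genes (636 at an unadjusted p under 0.05, 16 by DESeq2, 17 with the replicate number as a block and 82 with no filter on low counts), the smallest p being those of Lyn, Mcoln3 (-1.13 ± 0.19, adjusted p = 0.0689) and Ide (-0.88 ± 0.15, 0.073). Mcoln3 and Ide passed by DESeq2 (5.96e-05 and 0.00013), with the block (0.0192 and 0.018), with all 48 libraries in 1 model (0.0275 and 0.00152), with sex as a covariate (0.0428 each) and with no filter on low counts (3.23e-06 and 1.01e-10). They also passed without WT 4 (0.0338 and 0.023) or LynKO 4 (0.0431 and 0.0483), and Ide without LynAKO 4 (0.0458). Il12b with LPS was at -0.30 ± 0.27 in LynAKO and -0.66 ± 0.27 in LynBKO (adjusted p = 0.98 and 0.856, the latter 3.87e-07 with no filter on low counts). By DESeq2 the LPS counts were 9 and 28 and the LynAKO count with R848 was 5. With no filter on low counts these 3 counts were 84, 128 and 43, and with the replicate number as a block 5, 16 and 4. The LynBKO count with LPS was 2 without WT 1, 8 without LynAKO 1, 9 without WT 3 and 3 without WT 2, LynAKO 2, LynAKO 3, LynBKO 1, LynBKO 2, LynBKO 3 or LynKO 2. With R848 the LynAKO count was 0 without LynAKO 1 or 3, 2 without WT 2, WT 4 or LynAKO 4 and 3 without WT 3. The LynBKO count was 1 without WT 1 or LynKO 2, 2 without WT 2, WT 4 or LynAKO 4 and 4 without LynKO 4. Lama5 in LynAKO and Gm13835 and Ide in LynBKO with LPS each lost their call in 9 or more of 22 other settings (highest adjusted p = 0.25, 0.188 and 0.154). Atad2b in LynBKO lost it without WT 1 (0.0523) and with all 48 libraries in 1 model (0.0559).

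The isoform knockouts were then set against each other. edgeR called 0 genes between LynAKO and LynBKO without ligand (1173 at an unadjusted p under 0.05, 1 by DESeq2), 0 with LPS (353, and 0 by DESeq2) and 0 with R848 (445, and 0 by DESeq2). With no filter on low counts it called 191, 13 and 27. The smallest p without ligand belonged to Pltp, a phospholipid transfer protein gene (0.59 ± 0.12, SE, n = 4 against 4), Itgb7 (-0.54 ± 0.12) and Fabp4 (0.60 ± 0.13), each at an adjusted p of 0.584. By DESeq2 Pltp passed (0.0445), and with no filter on low counts all 3 did (1.12e-13, 4.87e-08 and 6.99e-05). Pltp came first with LPS too (0.61 ± 0.14, adjusted p = 1, but 2.41e-08 with no filter on low counts), and Oasl1 (-0.81 ± 0.20) and Stil (-0.85 ± 0.21) were among the first 3 with R848 (adjusted p = 1, and 0.0117 for Oasl1 with no filter on low counts). On simulated counts with the LynKO against WT design, edgeR recovered 67.2% of genes changed 1.5-fold and 76.1% of genes changed 2-fold. That simulation also held 66 genes changed 4-fold, and the adjusted threshold is stricter where fewer genes change. LynAKO against LynBKO was not simulated. The recovered shares therefore do not give the power of these comparisons, and 0 calls does not show that the isoform knockouts are alike.

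Each single knockout differed from the total knockout. Without ligand Top2a was lower by a log2 fold change of -1.04 ± 0.17 in LynAKO and -0.75 ± 0.17 in LynBKO than in LynKO (SE, n = 4 against 4; edgeR adjusted p = 0.00161 and 0.0136), and Mcm5 by -0.91 ± 0.17 and -1.01 ± 0.18. Il1b was higher by 1.29 ± 0.28 and 1.67 ± 0.28, Clec4n by 1.23 ± 0.19 and 1.24 ± 0.19, and the iron exporter gene Slc40a1 by 1.31 ± 0.14 and 1.29 ± 0.14. G2/M genes were lower in 41 of 53 in LynAKO (48 adjusted over the list alone; adjusted p = 0.0634 with an estimated correlation) and in 14 in LynBKO (43; adjusted p = 0.143 with an estimated correlation). With LPS, Il12b was higher by 1.27 ± 0.28 in LynAKO (adjusted p = 0.03, but 0.08, 0.107, 0.108, 0.0824 and 0.0662 without LynAKO 1, LynAKO 2, LynKO 2, LynKO 3 and LynKO 4). It was at 0.91 ± 0.28 in LynBKO (0.135). There it passed with sex as a covariate (0.88, 0.0412), with the replicate number as a block (0.89, 0.0281), with no filter on low counts (3.59e-14) and without LynAKO 4 (0.0398). For LynAKO edgeR called 474, 153 and 120 genes without ligand, with LPS and with R848, and for LynBKO 499, 88 and 241. DESeq2 called 759, 340 and 393 for LynAKO and 796, 344 and 677 for LynBKO, and edgeR with no filter on low counts 797, 457 and 426 and 851, 487 and 750. With the replicate number as a block the counts were 267 and 211 with LPS and 419 and 881 with R848. Without LynBKO NT 4 and LynKO NT 4 the untreated counts were 256 and 80. In that setting the call of Il1b in LynAKO was lost (adjusted p = 0.0712) and so was that of Top2a in LynBKO (adjusted p = 0.0828, and 0.0676 without LynBKO mouse 1). The LynAKO count without ligand was 303 without LynAKO 2 and 300 without LynKO 1. With LPS it was 32, 57, 87, 40, 60 and 89 without LynAKO 2, LynAKO 3, LynBKO 2, LynKO 2, LynKO 3 and LynKO 4. With R848 it was 21, 66, 42, 45, 64 and 58 without LynAKO 2, 3 and 4 and LynKO 1, 2 and 3. The LynBKO count without ligand was 171, 287, 277, 320 and 184 without LynBKO 1, 3 and 4 and LynKO 3 and 4. With LPS it was 144, 19, 36, 38, 42 and 28 without WT 1, LynBKO 1, 2 and 4 and LynKO 3 and 4. With R848 it was 124, 124, 25, 81, 70, 68, 138, 133 and 80 without LynAKO 2 and 3, LynBKO 1, 2 and 4 and LynKO 1, 2, 3 and 4.

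The knockouts share their WT libraries, so changes of the same sign need a reference. Of the genes called in LynKO without ligand, 94.4% had the same sign in LynAKO and 90.8% in LynBKO. The shares were 86.5% and 86.1% for unchanged groups simulated against the same WT libraries. In the simulation LynKO was unchanged too, and the share was taken over as many genes with the smallest p. Such genes are picked for noise in the shared WT libraries, which favours the same sign. The simulated shares are therefore too high a reference for genes that LynKO itself changed. With the WT libraries split, so that the comparisons share no library and unchanged genes would take either sign equally often, the shares were 87.3% and 82.7% for LynAKO and 87.4% and 85.1% for LynBKO. The covariance of log2 fold changes without ligand was 0.0673 for LynAKO with LynKO and 0.0775 for LynBKO with LynKO, against 0.0284 and 0.0282 in the simulation, and 0.0522 for LynAKO with LynBKO against 0.0285. With the WT libraries split the covariances were smaller, at 0.0285 and 0.0222 for LynAKO with LynKO, 0.0394 and 0.0319 for LynBKO with LynKO, and 0.00967 and 0.0109 for LynAKO with LynBKO. The simulated covariances arise from shared WT libraries, so they are no reference for the split ones, where no library is shared. With the WT libraries split, the median log2 change in the direction of LynKO was 0.17 and 0.12 in LynAKO and 0.21 and 0.17 in LynBKO. With LPS the same-sign shares were 96.8% in LynAKO and 96.3% in LynBKO (87.9% and 87.8% simulated), and with R848 95.5% and 87.9% (88.8% and 88.9% simulated). With the WT libraries split, the LPS shares were 93.8% and 78.6% for LynAKO and 96.4% and 79.4% for LynBKO. The R848 shares were then 82.6% and 89.5% for LynAKO and 85.2% and 79.8% for LynBKO.

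Without a block for the mouse, the test of whether a ligand response itself differed from WT gave few genes. With that block, which uses the pairing of the treatments by mouse, more genes were called for LynKO. Several of the genes called for LynKO without the block started lower and rose by a larger ratio, which need not mean a higher level with ligand. Acod1, the enzyme that makes itaconate, went from 16.4 ± 0.866 to 6610 ± 1130 CPM with LPS in LynKO and from 57.9 ± 12 to 8400 ± 586 in WT (SD, n = 4), a response larger by 1.47 ± 0.24 on the log2 scale (SE; edgeR adjusted p = 0.00426). The LPS response was also larger for Klhl21 (1.13 ± 0.20, adjusted p = 0.00426), Tlr2 (0.62 ± 0.11, 0.00426), Socs3 (0.95 ± 0.17, 0.00593), the death receptor gene Fas (0.84 ± 0.15, 0.00593) and the protease gene Mmp14 (1.13 ± 0.22, 0.0153). It was smaller for Palld (-1.16 ± 0.25, 0.0383) and the spindle checkpoint gene Mad2l1 (-0.77 ± 0.16, 0.0316). Tnf (0.35 ± 0.26, adjusted p = 0.835), Il1b (1.17 ± 0.32, 0.131), Cxcl10 (1.47 ± 0.36, 0.0713) and Lyn (-0.52 ± 0.12, 0.0521) did not pass in this model, which has no block for the mouse. Cxcl10 and Lyn passed by DESeq2 (adjusted p = 0.0226 and 0.00833), Lyn passed with sex as a covariate (0.0196), and Lyn and Il1b with only the 4 groups of the contrast (0.03 and 0.0409). Cxcl10 and Il1b passed with no filter on low counts (3.79e-22 and 2.79e-21). Their differences there, 1.51 and 1.21, were close to those of the main fit, and that setting was not tested on simulated data. With the mouse as a block Cxcl10 and Lyn passed (adjusted p = 0.0273 and 0.00263), and Il1b passed with LynBKO NT 2 and 3 exchanged as well (0.0157). Without LynAKO 1 Cxcl10 passed (0.0433), and without LynAKO 1, 2 or 4 or LynBKO 1 Lyn did (0.0427, 0.0329, 0.0459 and 0.0426). In the LPS response 14 genes were called (7 larger, 7 smaller) and the cytokine score of the response differed by -0.14 (exact permutation p = 0.371).

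The R848 response of LynKO was larger for Socs3 (1.13 ± 0.17, SE, n = 4 per group, edgeR adjusted p = 0.000577), Acod1 (1.35 ± 0.24, 0.00489), Mmp14 (1.25 ± 0.22, 0.00489), Tlr2 (0.55 ± 0.11, 0.0118) and Ier3 (0.94 ± 0.20, 0.0178). It was smaller for Frmd6 (-1.60 ± 0.25, 0.000577), Tmcc3 (-1.29 ± 0.21, 0.000601), Mki67 (-1.28 ± 0.28, 0.0299) and the ERK pathway inhibitor gene Spred2 (-1.01 ± 0.22, 0.0299). In all 27 genes were called, 12 larger and 15 smaller (9 and 18 with RLE scaling). With only the 4 groups of the contrast 3 genes were called for R848 and 22 for LPS. DESeq2 called 81 and 66, and edgeR with no filter on low counts 148 and 125. With the mouse as a block, by the labels' pairing of the 3 treatments of each mouse, 121 and 173 genes were called for LPS and R848. The LPS count was 7 without WT 4, 22 without LynAKO 1, 33 without LynAKO 4, 2 without LynKO 1 and 9 without LynKO 3. The R848 count was 7 without WT 1 and 12, 14 and 6 without LynKO 1, 2 and 4. Without LynBKO NT 4 and LynKO NT 4 the counts were 6 and 17. Of the genes named for the response differences, Acod1 and Klhl21 for LPS and Acod1, Frmd6 and Tmcc3 for R848 were called in all 25 other settings tried. For LPS the highest adjusted p over these settings was 0.0538 for Socs3 and for Tlr2 (without LynKO 1), 0.0992 for Fas, 0.109 for Mmp14, 0.241 for Palld and 0.175 for Mad2l1. For R848 it was 0.0713 for Socs3 and 0.107 for Tlr2 and Mmp14 (with only the 4 groups of the contrast), 0.21 for Ier3, 0.237 for Mki67 and 0.275 for Spred2.

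In the single knockouts edgeR called 0 response differences: LynAKO with LPS (366 at an unadjusted p under 0.05, 0 by DESeq2), LynAKO with R848 (328, and 2 by DESeq2), LynBKO with LPS (458, and 0 by DESeq2) and LynBKO with R848 (430, and 1 by DESeq2). With no filter on low counts it called 20 and 15 for LynAKO and 21 and 23 for LynBKO with LPS and R848. With R848 1 gene was called in LynAKO without WT 2 or LynAKO 2, and 1 in LynBKO without LynAKO 1 or LynAKO 4. Socs3 was at 0.72 ± 0.17 with LPS and 0.82 ± 0.17 with R848 in LynAKO (SE, n = 4 per group, adjusted p = 0.721 and 0.203), and Frmd6 with R848 at -1.09 ± 0.25 in LynAKO and -1.21 ± 0.25 in LynBKO (0.403 and 0.205). With R848 Socs3 in LynAKO passed by DESeq2 (0.00658) and without WT 2 or LynAKO 2 (0.0122 and 0.0144). Frmd6 passed by DESeq2 in LynAKO and LynBKO (0.0359 and 0.00856). In LynBKO it also passed with only the 4 groups of the contrast (0.0345) and without LynAKO 1 or 4 (0.0242 and 0.0295). Without the filter on low counts Socs3 passed in LynAKO with LPS and R848 (7.68e-05 and 2.88e-07), and Frmd6 with R848 in LynAKO and LynBKO (3.7e-08 and 4.22e-10). On counts simulated for the LynKO LPS response, edgeR recovered 37.3% of genes changed 1.5-fold and 71.6% of genes changed 2-fold. That simulation also held 66 genes changed 4-fold, and the responses of the single knockouts were not simulated. The recovered shares therefore do not give the power of the single knockout tests.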

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

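The tests of a wrong sex label and of another MHC haplotype were chosen after the result was seen, as was the reading of the test of chromosome segments.

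In 2 untreated libraries labelled female, male and female transcripts occurred together. The CPM of Xist and the Y-linked genes are not scaled by TMM. LynBKO NT 4 had Y-linked genes at 162 CPM and Xist at 147 CPM, and LynKO NT 4 had Y-linked genes at 89.6 CPM and Xist at 294 CPM, while the other 22 female libraries had Y-linked genes at 0 to 0.654 CPM and Xist at 294 to 489 CPM and the 24 male libraries Y-linked genes at 157 to 332 CPM. A wrong sex label alone would leave 1 of the signals near 0, but the lowest share, relative to libraries of that sex, was 32%. The Xist and Y shares summed to at most 118%, as a mixture with a male library of the same genotype may give. If that male library belongs to the same group, the mixed library is not independent of it, which would narrow the spread within the group. RNA of another genotype in LynKO NT 4 is argued against, since it lay at 0.967 on the line from WT to the other LynKO libraries (0.864 to 0.915 for these). WT RNA in LynBKO NT 4 is argued against too, with Lyn at 122 CPM where the mixture would give 164 CPM, but LynAKO RNA (Lyn at 118 CPM) stays open. Whether cells, RNA or libraries were mixed was not tested, and no biological explanation was tested.

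WT mouse 1 lay apart from all other mice at MHC genes. In the window from 33 to 37 Mb of chromosome 17, 10 of 150 tested genes had all 3 libraries of WT 1 outside all other libraries of their treatment, among 130 such genes genome-wide (one-sided Fisher exact p = 1.32e-06), and the highest number in the window for another mouse was 9, of 588 genes, in LynKO 4. Another MHC haplotype in this mouse is a candidate explanation, seen and tested on the same data. More antigen-presenting cells of another type would raise their other genes too, but the median log2 difference of the other MHC II and dendritic cell list members was at most 0.02, beside 4.97, 4.54 and 3.81 for Cd74 without ligand, with LPS and with R848. Cd74 lies on chromosome 18, outside the window, so a haplotype of the window would not cover it directly.

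Besides Lyn, Gm13835, H2-Q6 and Ide had all 12 knockout mice on 1 side of all 4 WT mice in all 3 treatments. Their median ratio of the LynKO change to the single knockout change was 1.04 (SE 0.162), beside 2.90 for Lyn. The genes were picked because the single knockout mice too lay apart from WT, which favours a ratio near 1. The ratio therefore cannot decide whether their change grows with the loss of Lyn. Segments that differ between the WT and knockout mice remain open. The test for them found 0 pairs of these genes within 1 Mb, but random sets had a median of 0 pairs and at most 1, so that bound could decide nothing. H2-Q6 has close paralogs, so its counts are uncertain. It is also among the MHC genes at which WT 1 lay below all other mice (0, 10.6 and 6.37 CPM without ligand, with LPS and with R848).

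Some libraries lay far from the other 3 of their group by Dixon's test, in 6 of 72 groups tested, where chance gives about 1 in 20 groups. WT LPS 2 had 22.6 M counts in all (16.1 to 16.6 M in the others). Lyn stood at 257 CPM in LynAKO LPS 2 (206 to 208). The G1/S score was 2.67 in LynAKO R848 1 (2.10 to 2.16). The G2/M score was 1.89 in WT NT 1 (2.52 to 2.61), 2.68 in WT R848 3 (2.57 to 2.58) and 2.60 in LynBKO NT 1 (2.95 to 3.00).

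The response of LynKO differed from that of WT by the test of the difference itself, for 14 genes with LPS and 27 with R848, Acod1 among both. With the mouse as a block the counts were 121 and 173.

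Splits of the same 8 mice or libraries into other groups of 4 were counted, 35 per comparison with the real split included. Other splits mix the 2 real groups, so a real difference widens their spread and lowers their counts. Low counts in them therefore say little about chance, and no share can fall below 1 of 35. For all 8 ligand comparisons only the real split gave as many genes, 1 of 35, and the highest other count was 1 (R848 in WT) or 0. For LynKO against WT the real counts of 1385, 1187 and 829 genes without ligand, with LPS and with R848 were each reached by the real split alone, 1 of 35, with highest other counts of 0, 0 and 15. The same held for LynAKO against LynKO (474, 153 and 120 genes, highest other 1, 57 and 2), LynBKO against LynKO (499, 88 and 241, highest other 0 each), LynBKO against WT without ligand and with LPS (9 and 5, highest other 2 and 0) and the LynKO responses (14 and 27, highest other 1 and 2). Chance is not ruled out for the number of genes called for LynAKO against WT, where 2 splits gave as many as the 4, 3 and 1 genes called (highest other 15, 4 and 1). The splits count genes and do not bear on single calls such as that of Lyn, the gene knocked out, which was called in each treatment. For the other comparisons the splits alone do not settle whether the counts arose by chance. Where edgeR called 0 genes, all 35 splits gave as many: LynBKO against WT with R848 (highest other 0; 636 at an unadjusted p under 0.05, 16 by DESeq2), LynAKO against LynBKO in each treatment (highest other 0; 1173, 353 and 445 unadjusted, 1, 0 and 0 by DESeq2), and the LPS and R848 responses of LynAKO (highest other 0 and 1; 366 and 328 unadjusted, 0 and 2 by DESeq2) and LynBKO (highest other 2 and 5; 458 and 430 unadjusted, 0 and 1 by DESeq2). Of the 35 splits, 8 part all 4 numbers, which for responses pair the libraries of a mouse by the labels. For LynAKO against WT the highest other count among these 8 was 0 in each treatment, where no share can fall below 1 of 8.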

How the results depend on the processing

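The settings without the LynBKO NT 4 and LynKO NT 4 libraries and the list scores with 1 library left out were added after the data were seen; all others were planned. Direction was checked for 328 named results of single genes and 165 list tests. None of their calls changed direction in any setting. Results without a call could change sign, as Ifit1 did for R848 in WT (-0.48 to 0.44). The ligand counts stayed within 1.5 times the reported ones in all 90 alternatives, as did all 32 counts with RLE size factors and the counts of LynKO against WT without ligand and with LPS in all settings that kept every mouse. Where counts moved further the cause was not tested, except that settings that leave out libraries have fewer of them.

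With DESeq2, without ligand, 12 genes were called for LynAKO against WT, 124 for LynBKO against WT, 1 for LynAKO against LynBKO, 759 for LynAKO against LynKO and 796 for LynBKO against LynKO. With LPS it called 9, 28, 340 and 344 (LynAKO and LynBKO against WT, then against LynKO), and with R848 5, 16, 393 and 677, and 1250 for LynKO against WT. For response differences it called 2 for LynAKO and 1 for LynBKO with R848, and 66 and 81 for LynKO with LPS and R848.

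With no filter on low counts the calls without ligand were 124 and 445 for LynAKO and LynBKO against WT, 191 between them, and 797 and 851 against LynKO. With LPS they were 84, 128, 13, 457 and 487 in that order, and with R848 43, 82, 27, 426 and 750. The response differences were 20 and 15 for LynAKO, 21 and 23 for LynBKO and 125 and 148 for LynKO with LPS and R848. This setting was not tested on simulated data, so these counts are uncertain.

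With the replicate number as a block, which stands for the mouse only in responses and ligand comparisons, the calls for LynAKO and LynBKO against WT were 2 and 14 without ligand, 5 and 16 with LPS and 4 and 17 with R848, those against LynKO 267 and 211 with LPS and 419 and 881 with R848, that of LynKO against WT with R848 1753, and the LynKO responses 121 and 173. With LynBKO NT 2 and 3 exchanged the LynKO responses were 149 and 198, and 68 and 109 without LynBKO NT 4 and LynKO NT 4 as well.

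With all 48 libraries in 1 model the calls were 7 for LynAKO against WT without ligand, 3 for LynBKO against WT with LPS, 259 and 185 for LynAKO and LynBKO against LynKO with LPS, and with R848 4 and 9 against WT, 1406 for LynKO against WT and 376 and 654 against LynKO. With sex as a covariate they were 158 for LynBKO against LynKO with LPS, 3 for LynBKO against WT and 186 for LynAKO against LynKO with R848, and 28 for the LynKO LPS response. With only the 4 groups of the contrast they were 1 for the LynBKO R848 response and 22 and 3 for the LynKO responses. Without LynBKO NT 4 and LynKO NT 4 they were 3 for LynBKO against WT, 256 and 80 for LynAKO and LynBKO against LynKO without ligand, and 6 and 17 for the LynKO responses.

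Leaving out 1 mouse gave, without ligand, 2 to 7 genes for LynAKO and 3 to 29 for LynBKO against WT, and 300 to 573 and 171 to 619 against LynKO. With LPS it gave 2 to 9 for LynBKO against WT, 663 to 1271 for LynKO against WT, and 32 to 182 and 19 to 144 against LynKO. With R848 it gave 0 to 3, 0 to 4 and 464 to 873 against WT for LynAKO, LynBKO and LynKO, and 21 to 180 and 25 to 335 against LynKO. The R848 responses of LynAKO and LynBKO gave 0 to 1, and those of LynKO 2 to 33 with LPS and 6 to 38 with R848.

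Of 6419 values of 328 named results of single genes under other settings, 5920 kept their side of the threshold, 325 lost the call, 141 gained one, 33 without a call moved and 0 reversed. Of 495 list tests under other settings, 372 kept their side, 74 lost the call (64 with an estimated correlation), 40 gained one and 9 moved. With a prior count of 0.5, 70 of 72 list scores were the same and 2 moved, and with 1 library left out 251 score differences stayed within 1.5 times the full one and 133 moved. Depth limits genes near 0, such as Ifnb1 and untreated Il6 and Il12b.

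Of 402 alternative counts of genotype comparisons 269 stayed within 1.5 times the reported count and 133 moved, and of 150 for response differences 115 stayed and 35 moved. Of 14 overlap shares with the WT libraries split, 3 were the same and 11 moved, each split leaving 2 WT libraries per comparison.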

Other observations

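The genes named in this part were chosen after the result was seen; the list tests were planned.

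Further single genes differed from WT in untreated LynKO macrophages. The scavenger receptor gene Cd36 rose by 1.04 ± 0.19 and the lipid regulator gene Pparg by 1.06 ± 0.14, while Apoe fell by 0.70 ± 0.16 and Fabp4 by 0.88 ± 0.13 (log2, SE, n = 4 against 4; edgeR adjusted p = 0.00129, 7.43e-05, 0.00708 and 0.000148). Among Toll-like receptors and adaptors 3 of 31 rose and 4 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.0911), with Tlr2 at -0.78 ± 0.09. The R848 receptor gene Tlr7 was at -0.45 ± 0.12 (adjusted p = 0.0227, but 0.0635 without WT 1 and 0.0739 without LynKO 4). Its call was also lost with all 48 libraries in 1 model (0.102) and without the LynBKO NT 4 and LynKO NT 4 libraries (0.091). The flagellin receptor gene Tlr5 was at 0.89 ± 0.23 (0.0159, but 0.0551, 0.0615 and 0.0805 without WT 1, WT 4 and LynKO 2). Its call was lost with all 48 libraries in 1 model too (0.104). Interferon-stimulated genes fell in 5 of 54 cases (5 adjusted over the list alone; camera adjusted p = 0.838), the GTPase gene Gbp2 (-1.21 ± 0.26) among them.

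Immediate-early genes rose in 5 and fell in 4 of 27 cases (8 and 7 adjusted over the list alone; camera adjusted p = 0.656), with Ier3 at -1.11 ± 0.09, Fos at 0.65 ± 0.09 and Nr4a1 at 0.70 ± 0.16. Genes of ERK pathway output rose in 6 and fell in 1 of 17 (8 and 2 adjusted over the list alone; adjusted p = 0.415 with an estimated correlation). Of these Egr1 was at -1.81 ± 0.37 and the ERK phosphatase gene Dusp5 at 0.84 ± 0.17. G1 cyclins and CDK inhibitors rose in 3 of 19 (5 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.395). FoxO targets rose in 3 and fell in 3 of 20 (3 and 4; camera adjusted p = 0.115). Src-family kinases and regulators rose in 2 and fell in 3 of 33 (2 and 4; camera adjusted p = 0.395), with Fyn at 0.42 ± 0.07. The p53 targets fell in 4 of 18 (3 rose and 8 fell adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), with Fas at -1.04 ± 0.14.

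Monocyte markers rose in 1 and fell in 2 of 15 (1 and 4 adjusted over the list alone; camera adjusted p = 0.0588), with the haptoglobin gene Hp at -1.74 ± 0.24. Neutrophil markers fell in 2 of 10 (2 adjusted over the list alone; 0.173). B cell markers fell in 2 of 4 (3 fell and 1 rose adjusted over the list alone; 0.0941), with Ighm at -0.97 ± 0.20 and Cd22 at -0.88 ± 0.24; the call of Cd22 was lost without WT 1, WT 4, LynKO 1 and LynKO 2 (adjusted p = 0.0641, 0.0809, 0.0635 and 0.0774). Alternative activation genes rose in 1 of 14 (1; 0.838), osteoclast markers rose in 1 and fell in 1 of 14 (2 and 2; 0.845), and MHC II and dendritic cell genes fell in 1 of 18 (1; 0.705). Hypoxia and glycolysis genes rose in 2 and fell in 1 of 29 (2 and 3; 0.831) and heat shock genes rose in 2 of 12 (2 rose and 1 fell; 0.605). Mitochondrially encoded transcripts rose in 1 of 13 (0 adjusted over the list alone by edgeR; adjusted p = 0.415 with an estimated correlation). The mast cell, megakaryocyte, stromal and cholesterol synthesis lists had camera adjusted p of 0.770, 0.748, 0.254 and 0.697.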
